A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

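The data are 4 Agilent tiling arrays of fission yeast (Schizosaccharomyces pombe), 1 array for each of 4 strains: wild-type, clr3-735, asf1-1 and the double mutant asf1-1clr3-735. Per the labels, log-phase cultures in rich medium at 30 °C were fixed with 1% formaldehyde, spheroplasts were digested with micrococcal nuclease, and gel-purified mononucleosomal DNA was labelled with Cy5 against Cy3-labelled genomic DNA of the same strain. Each array held 45220 features, of which 43993 were probes of 60 bases spaced 10 bp apart with an overlap of 50 bases. Per the file headers, wild-type and clr3-735 shared slide 1 and its scan, and asf1-1 and the double mutant shared slide 2 and its scan, so the asf1-1 allele and the slide cannot be told apart.

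Per the file headers, the authors extracted the images with Agilent Feature Extraction 10.7.3.1, which subtracted background, removed spatial trends and applied 1 linear dye factor per channel, with no lowess step. The deposited processed signals of both channels are intensities on a linear scale, as are the deposited spot medians, background values and background-subtracted signals. The deposited log ratio is the log10 of processed Cy5 over processed Cy3 and was used only as a check. The deposited spot flags (saturated, well above background, non-uniform, population outlier, manual) hold 0 or 1. The steps between the fixed cells and the labelled DNA that the labels leave open are not given in the sources used here.

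The value analysed is the log2 ratio of processed Cy5 to processed Cy3. Control spots and spots with an outlier, non-uniform or manual flag were left out, which removed 111 probes from the wild-type array, 249 from clr3-735, 1020 from asf1-1 and 1015 from the double mutant. Each array was then centred on the median of its non-control probes. Signal was well above background in both channels for 99.9% of probes on each array. Cy5 was saturated at 13.8% of the wild-type probes and 13.3% of the clr3-735 probes, and Cy3 at 1.56% and 1.40%, while 0 probes were saturated on slide 2. A saturated Cy5 spot understates the ratio, so a slide 2 value minus a slide 1 value is an upper bound at such spots. The clr3-735 minus wild-type difference and the interaction hold saturated spots on both sides and are bounds in neither direction. In the rDNA, Cy3 was also saturated, at 24.9% of the wild-type and 21.7% of the clr3-735 probes, so no rDNA value that uses slide 1 is a bound. With 1 array per strain there was no replicate against which to check a difference, and the number of arrays limits the precision of every value.

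Probe positions are printed in the coordinates of the array design. These were compared with the ASM294v3 reference by predicting Cy3 from sequence composition (r = 0.629 between predicted and measured signal on a chromosome arm not used to fit the model) and searching for the offset of best match: 123 of 134 windows lay within 10 bp of the position that follows when an assembly gap of 1000 bp in the design is read as 100 bp in the reference. Gene coordinates are those of the ASM294v3 annotation. The mating-type region lies on a separate contig of 41250 bp; its left flank was placed by 16 of 18 windows and its right flank by 4 of 5, and 59.1% of the mating-type probes lie in sequence absent from the reference.

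For each region the median over probes of the difference between strains was computed. The intervals of region differences in the report are 95% order-statistic intervals over the medians of 1 kb windows; those of the tests of explanations are over probes unless windows are named, which are narrower because neighbouring probes overlap. The alternatives were judged against the intervals over probes. The inv1 block had 4 windows, too few for a 95% interval, so the lowest and highest window medians are given for it. None of these intervals or ranges covers differences between cultures. Each median was ranked among 10000 random contiguous runs of the same number of probes with a mean log2 ratio within 0.15 of that of the region, and named as outside the random runs when below 2.5% or above 97.5% of them. The matched mean was over all 4 arrays, including those compared. Matching can therefore select runs that differ between strains as the region does, which limits every rank among matched runs. The band of 0.15 and the minimum of 100 matching start positions, below which no percentile is given, were chosen after seeing the data, as was a second ranking against runs at any level. The runs of both rankings were kept clear only of the region being ranked, so they could include the rDNA and other regions that differed. Gene values used genes with at least 3 probes. Genes were counted at or beyond 0.5 in size, with no test. Fixed gene lists were ranked among 10000 random lists of the same size matched on mean log2 ratio in 5 classes. That mean was over all 4 arrays, and the random lists could hold the list's own members. Effects of each allele over genes, which pair the clr3-735 effect by slide, were fitted with limma on the mean over each gene's probes, with both alleles as additive terms over the 4 arrays; this leaves 1 residual degree of freedom, takes the interaction as error, and gave infinite prior degrees of freedom, so that every gene had the same standard error. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05 and measure only the spread between these 4 arrays. The effects of one allele in both backgrounds were correlated across genes, with 10000 circular shifts along the genome as the chance level. Profiles around gene starts and ends used bins of 50 bp out to 1000 bp. At gene starts the depth was the median from -200 to 0 bp minus that from 0 to 1000 bp. At gene ends it was the median from 0 to 200 bp minus that from -1000 to 0 bp. Intervals of the depth at gene starts are over the overlapping probes from -200 to 0 bp alone, with the other median held fixed. They are therefore too narrow.

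The genes named per comparison were fixed by rule: for each mutant, up to 10 protein-coding genes a direction with the largest median difference among those whose probes all moved one way; for each allele, up to 5 genes a direction with the largest change past the limma threshold; and up to 4 members of each gene list. Genes named outside that rule were chosen after their values were seen, and the text says so. The rule also names asf1 and clr3, but the array does not cover them. The strains' genomic DNA was compared in Cy3 alone, with a limit of -2 for a candidate sequence difference. The outer repeats, central domain, mating-type region, subtelomere, rDNA, tRNA genes and euchromatin were chosen before the data were examined. So were the lists, the comparisons between strains and most alternatives. The inv1 block, centromeric tRNA clusters, chromosome II arms, left part of the contig, long terminal repeats and other blocks and boundaries were not among the regions fixed beforehand. Of the tests of explanations, 5 of 8 were chosen after, as were all further observations.

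The alternatives were normexp background correction with an offset of 50, loess within each array, quantile normalization between arrays, centring on coding probes, equal spread of the arrays, removal of the GC trend (loess with a span of 0.3), leaving out dim or saturated probes, probes with 1 genome match, means in place of medians, at least 5 probes per gene, sizes of 0.3 and 1, a subtelomere of 25 kb, a start window from -150 to 50 bp, and limma with trend and robust options. Normexp used spot medians, since the files hold no spot mean. Chosen after seeing the data were the runs at any level, the loess, quantile and coding-probe settings for the gene lists and for the correlations across genes, and those correlations over protein-coding genes.

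The code was tested on simulated data. In a first draw of 200 genes the limma fit called 42.9% of those given a change of 0.5, 100% of those given 1 or 2, and 0% of unchanged genes. The outcome varied: over 50 further draws the medians were 21.4% (0 to 57.1%), 85.7% (0 to 100%), 100% (0 to 100%) and 0.633% (0 to 3.80%) for changes of 0.5, 1, 2 and 0. A region shift of 0.3 came back as 0.256. In the first draw 10 of 100 unshifted regions fell outside the random runs, and in 10 further sets of 100 the median was 6 (5 to 14), against a nominal 5%. The 95% interval held the true median in 95.7% of simulations. Those simulations drew independent values, so this coverage does not carry over to intervals over overlapping probes or neighbouring windows. The noise of the unshifted regions was shared only between close neighbours on a long unbroken stretch. The share called may therefore differ on these arrays. Of the circular shifts, 0% reached the correlation of a shared effect and 56.3% that of unrelated effects. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8.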

Results

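The 4 arrays measured how much mononucleosomal DNA, relative to genomic DNA, was recovered along tiled parts of the fission yeast genome: centromere 2 with its flanking arms, the mating-type region, the subtelomere of chromosome I, the rDNA end of chromosome III and a few gene blocks. Asf1 is a histone chaperone, and Clr3 is the histone deacetylase of the SHREC silencing complex. The series title concerns Asf1 and HIRA, histone deacetylation and nucleosome occupancy in heterochromatin, and the comparisons ask how occupancy in each mutant differed from wild-type and whether the double mutant differed from each single mutant. Each group holds 1 array, so no difference was checked against replicates. Median signals were 1477 in Cy5 and 1246 in Cy3 for wild-type, 1426 and 1224 for clr3-735, 889 and 841 for asf1-1, and 1146 and 924 for the double mutant. The standard deviation of the log2 ratio was 0.71 in wild-type, 0.73 in clr3-735, 0.90 in asf1-1 and 1.05 in the double mutant. Across probes, which are not independent, the arrays of slide 1 correlated at r = 0.931 and those of slide 2 at 0.899, against 0.799 for asf1-1 with wild-type and 0.729 for the double mutant with clr3-735.

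In asf1-1, occupancy was lower than in wild-type over the central domain of centromere 2, the part of the centromere between the outer repeats (chromosome II, 1620101 to 1631920, 1177 probes). The median difference was -0.46 on the log2 scale (interval -0.52 to -0.42), from a level of -0.26 in wild-type to -0.73 in asf1-1. Taken apart, Cy5 was at -0.28 and the genomic DNA in Cy3 at 0.12, so part of the difference lies in the genomic DNA channel. The tRNA clusters that border the centromere (781 probes between 1598901 and 1649150) were lower by a median of -0.57, with 14.6% of them saturated on the wild-type array. The mating-type region (contig, 18731 to 40770, 2199 probes) was lower by -0.22 (interval -0.41 to -0.09). The rDNA (chromosome III, 1 to 23130, 2302 probes) was higher by 0.56 (interval 0.38 to 0.69), from -0.24 in wild-type to 0.23 in asf1-1. Over the outer repeats (chromosome II, 1603321 to 1645640, 2933 probes), which carry the pericentromeric heterochromatin, the difference was 0.05, and over the subtelomere of chromosome I (1 to 50000, 4889 probes) it was -0.06. The chromosome II arms differed by -0.08. Over the alternatives run, the central domain ranged from -0.64 (normexp) to -0.25 (loess), the mating-type region from -0.39 (normexp) to -0.10 (loess) and the tRNA clusters from -0.83 (normexp) to -0.33 (probes with 1 genome match).

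Ranked against matched random runs, the central domain in asf1-1 lay at 45.1%, but only 2 separate stretches of the array matched its level; among runs at any level, a ranking chosen after seeing the data, it lay at 1.60% of 31 separate stretches. The rDNA lay above all runs (100%) in both rankings, with 7 matching stretches, but turned to -0.04 with loess within arrays. The mating-type region lay at 10.5% among 14 separate stretches and was not outside them, and no percentile was given for the outer repeats and the subtelomere, which had too few matching runs. Saturated probes on slide 1 made up 60.5% of the outer repeats and 29.7% of the subtelomere in wild-type, so those differences are only upper bounds. Over the unsaturated probes the outer repeats turned to -0.25 and the subtelomere stood at -0.17; with the arrays centred anew on unsaturated probes these were -0.18 and -0.11. The mating-type region, with 15.1% of its probes saturated in wild-type, is an upper bound too and was at -0.30 over unsaturated probes. The rDNA had saturated probes in both channels (78.4% in either), so its value is no bound; over its 316 unsaturated probes it was 0.36.

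**Figure D1:**
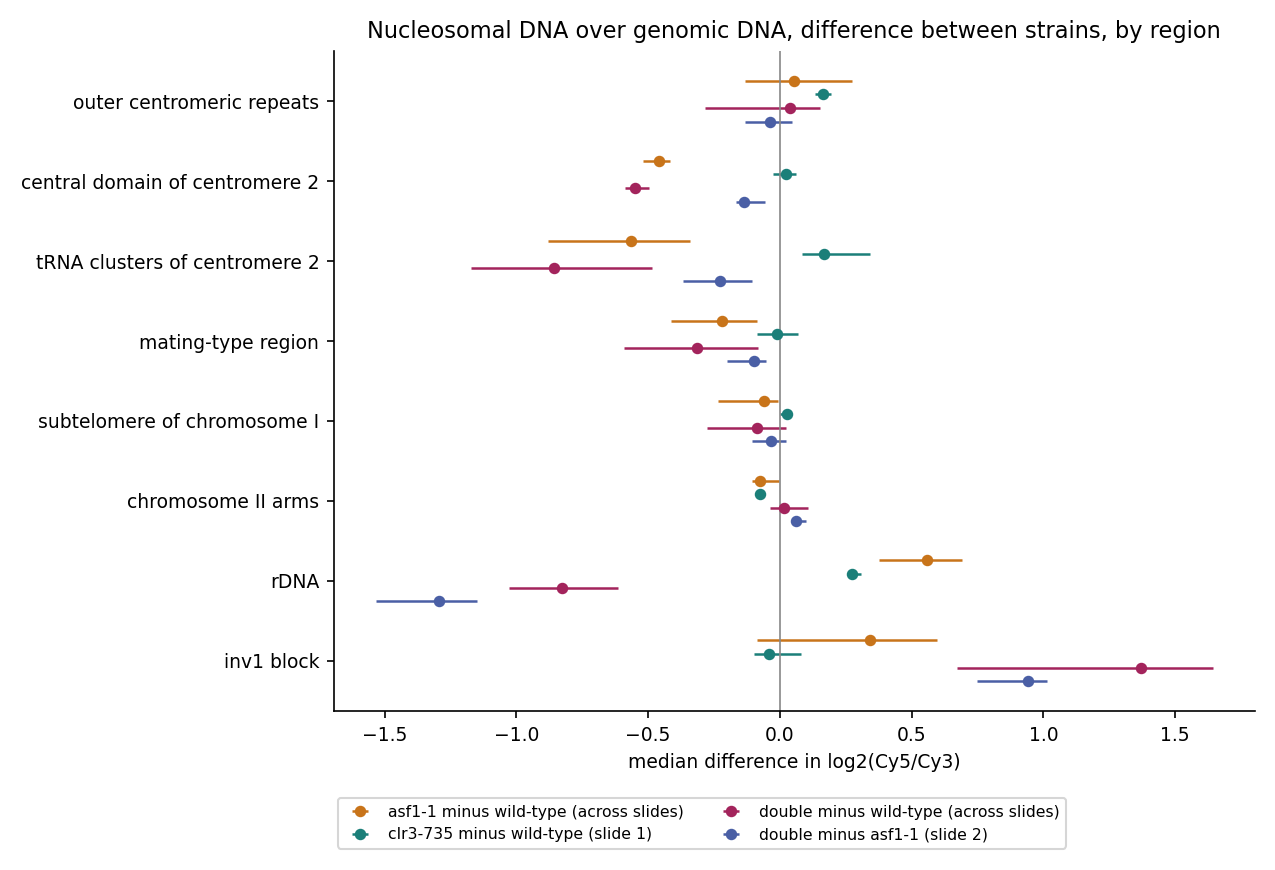
Median difference in log2(Cy5/Cy3) between strains (x axis, log2 units) for 8 regions (y axis); points are medians over the region's probes, and bars are 95% order-statistic intervals over 1 kb windows. For the inv1 block, which has 4 windows, the bars run from the lowest to the highest window. The central domain of centromere 2 lies at -0.46 in asf1-1 and -0.55 in the double mutant, each minus wild-type, against 0.02 in clr3-735; the double mutant minus asf1-1 value of -0.14 turns positive when the spread of the arrays is made equal, and the outer repeats and rDNA of asf1-1 change sign in other settings.

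**Figure D2:**
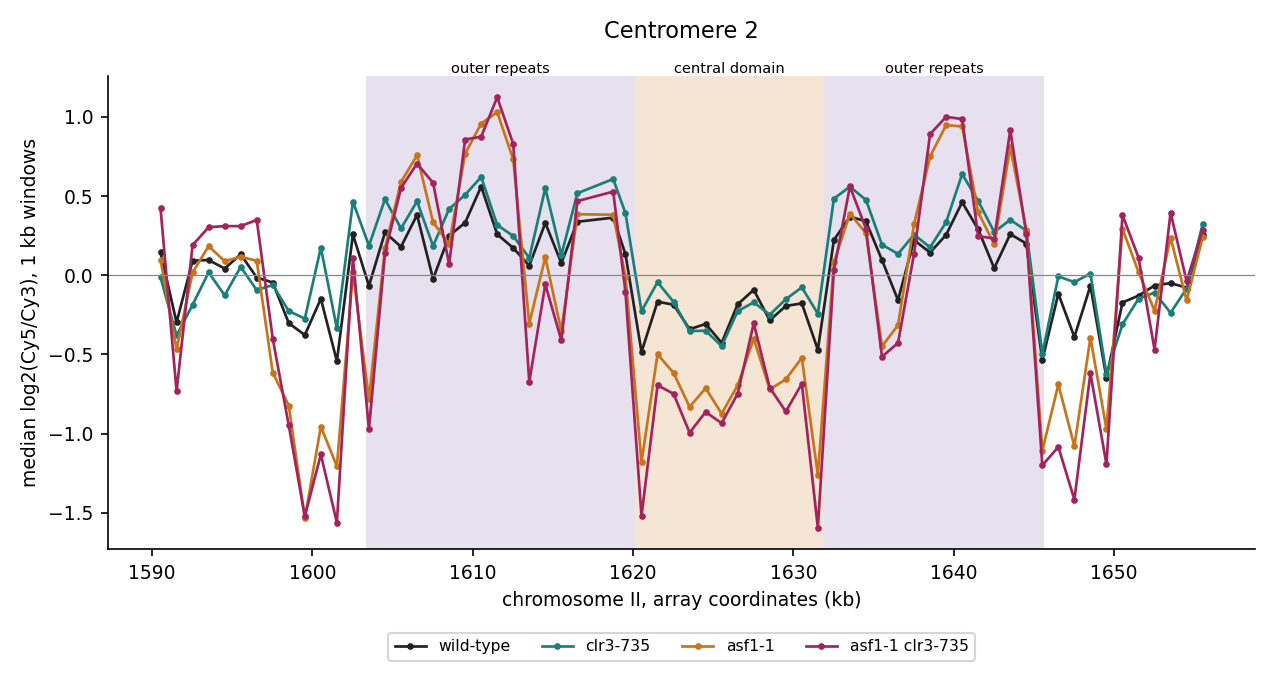
Median log2(Cy5/Cy3) in 1 kb windows (y axis) along centromere 2 (x axis, chromosome II in kb of array coordinates); lines are the 4 strains and shading marks the outer repeats and the central domain. Over the central domain the wild-type level was -0.26, clr3-735 -0.22, asf1-1 -0.73 and the double mutant -0.85.

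Among 204 genes, 41 had a median at least 0.5 lower in asf1-1 than in wild-type and 5 at least 0.5 higher. All 32 tRNA genes were among the lower ones, with a list median of -0.80. This lay below every matched random list (0%), although those lists were themselves low (95% between -0.62 and -0.54). The random lists could hold tRNA genes themselves, so this rank says little about tRNA genes against other genes. The tRNA genes were saturated at 35.8% of their probes in wild-type, which gives a bound. The 3 protein-coding genes past that size were SPBC21B10.15 (-0.64), mug124 (-0.58) and fba1 (-0.57). Fba1 (SPBC19C2.07, chromosome II, 1688321 to 1689599), fructose-bisphosphate aldolase of glycolysis, and atg12 (SPAC1783.06C, chromosome I, 2199327 to 2200120), an autophagy protein, at -0.45, were lower at all of their probes. The array covers only an end of atg12, so its values here and below refer to that end. SPBC21B10.15 and mug124 were named after their values were seen.

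Ribosomal protein genes had a list median of 0.32 over 5 members in asf1-1, above 99.6% of matched random lists, with 0 of them past 0.5; rpl26 was higher by 0.35 and rpl802 by 0.33, while rpl4302 stood at -0.22. The 22 subtelomeric genes had a median of -0.04 at 13.8% of random lists. Single list members gave 0.26 for tas3, a subunit of the RITS silencing complex, -0.16 for pht1, the histone variant H2A.Z, and 0.12 for the 5S rRNA gene SPRRNA.33. In the snRNA and snoRNA list (4 members, median -0.28, 59.2% of random lists), snR92 was at -1.02 and snoZ15 at 0.43. The mating and nitrogen starvation list had 2 members, isp4 at 0.07 and inv1 at 0.32, with a median of 0.20 at 86.5%. The lists for meiosis, stress, heat shock, iron, phosphate, wtf genes and Tf2 elements had 0 members on the array, and mitochondrial DNA was not analysed here.

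In clr3-735, compared with wild-type within slide 1, the central domain differed by 0.02 (interval -0.03 to 0.06), the mating-type region by -0.01 (interval -0.09 to 0.07) and the subtelomere by 0.03. The outer repeats were higher by 0.16 (interval 0.13 to 0.19), the centromeric tRNA clusters by 0.17 and the rDNA by 0.27. These regions had many saturated probes on both arrays, with 60.5% of the outer repeats, 14.6% of the clusters and 78.4% of the rDNA in wild-type, so the values are bounds in neither direction; over unsaturated probes they were 0.14, 0.14 and 0.48. With loess within arrays they were 0.04, 0.13 and 0.0058, so the outer repeat and rDNA differences depend on that setting. The chromosome II arms were at -0.08, and the contig left of the mating-type region (1 to 18720) at -0.13. With arrays centred on coding probes these were 0.04 and -0.01.

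Matched random runs placed the rDNA and the tRNA clusters of clr3-735 above all runs (100%) and the left part of the contig below all of them (0%), with 7, 5 and 15 separate stretches; the tRNA clusters lay at 91.7% among runs at any level. Taken apart, the left outer repeats (0.17) lay above all matched runs (100%) and the right ones (0.15) at 70.3%, each from 3 separate stretches, with 93.2% and 90.0% among runs at any level. The mating-type region lay at 78.1%. The central domain lay above all matched runs, but from 2 separate stretches, and at 78.2% of runs at any level.

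Of 204 genes, 7 were at least 0.5 higher in clr3-735 than in wild-type, all of them tRNA genes, and 0 were as much lower. The tRNA list had a median of 0.38, with 39.4% of probes saturated in clr3-735, and was at 0.18 with loess within arrays. It lay above all random lists (100%), which could again hold tRNA genes themselves. Ribosomal protein genes had a median of -0.22, at 0.03% of random lists, with rpl4302 at -0.35 and rpl26 at -0.29; it was -0.10 when arrays were centred on coding probes. Subtelomeric genes had a median of 0.02 at 99.2% of random lists, which turned to -0.02 with loess within arrays and to -0.01 with equal spread. The snRNA and snoRNA list had a median of -0.03 (9.14%) and the mating and nitrogen starvation list -0.06 (37.1%). The protein-coding genes whose probes were all higher were atg12 at 0.22 and mat3-Mi (SPBC1711.01C, chromosome II, 2132586 to 2132714), a gene of the silent M cassette, at 0.13; all mat3-Mi probes match several places. Tas3 stood at -0.10, pht1 at -0.12, fba1 at -0.25 and SPRRNA.33 at 0.25.

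In the double mutant, occupancy was lower than in wild-type over the central domain by a median of -0.55 (interval -0.59 to -0.49), over the centromeric tRNA clusters by -0.86 and over the mating-type region by -0.32 (interval -0.59 to -0.08). The outer repeats differed by 0.04 and the subtelomere by -0.09. The rDNA was lower by -0.83, and a block around inv1 (chromosome III, 1724400 to 1727399, 295 probes) was higher by 1.37 (range of its 4 windows 0.67 to 1.64). The saturated shares of slide 1 given above make the tRNA cluster, outer repeat, subtelomere and mating-type values upper bounds, while the rDNA value is no bound. Over unsaturated probes the outer repeats turned to -0.31, the subtelomere moved to -0.24, the mating-type region to -0.43 and the rDNA was at -0.98. The genomic DNA channel took part in these differences: Cy5 and Cy3 were at 0.92 and -0.40 over inv1, 0.07 and 0.89 over the rDNA, -0.46 and 0.11 in the central domain, -0.23 and 0.10 in the mating-type region, -0.66 and 0.18 in the tRNA clusters, and 0.25 and 0.21 in the outer repeats. Over the alternatives run, the central domain ranged from -0.85 (coding-probe centring) to -0.22 (quantile normalization), with -0.27 under loess, -0.30 with equal spread and -0.31 with the GC trend removed. The mating-type region ranged from -0.62 (coding-probe centring) to -0.13 (loess), the tRNA clusters from -1.16 to -0.39 and the rDNA from -1.13 to -0.39 (both coding-probe centring to quantile), and the inv1 block from 0.93 (equal spread) to 1.57 (normexp).

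The inv1 block lay above all matched runs (100%, 12 separate stretches) and the rDNA below all of them (0%, 7 stretches), in both rankings. The inv1 block and the tRNA clusters were not among the regions fixed beforehand. The tRNA clusters lay at 0% of matched runs and 1.66% of runs at any level, the central domain at 0% (2 stretches) and 5.45%, and the mating-type region at 7.80%, inside the random runs. Those runs could include the rDNA, itself lower, so this rank does not show that the mating-type region was unchanged. Centring on coding probes lowered every double mutant minus wild-type value by about the same amount (-0.30).

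**Figure D3:**
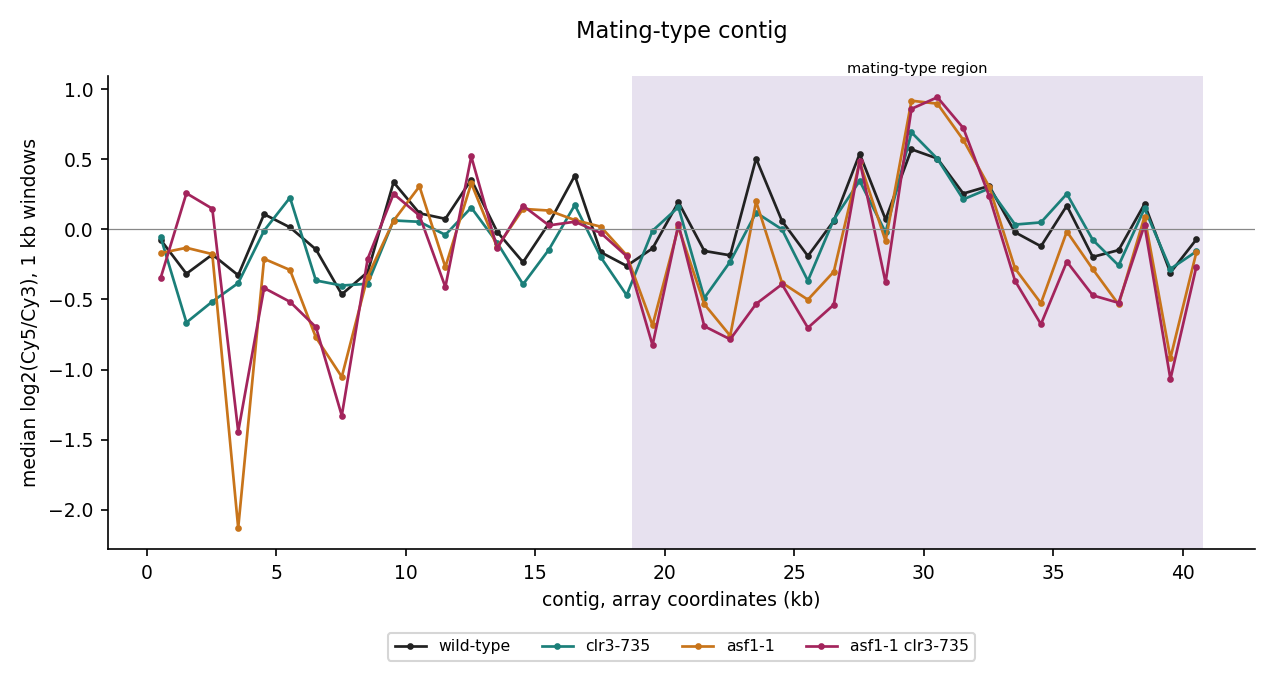
Median log2(Cy5/Cy3) in 1 kb windows (y axis) along the mating-type contig (x axis, kb of array coordinates); lines are the 4 strains and shading marks the mating-type region. Over that region the wild-type level was 0.09, clr3-735 0.07, asf1-1 -0.15 and the double mutant -0.26.

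Among genes, 51 were at least 0.5 lower in the double mutant than in wild-type and 12 at least 0.5 higher, including 6 lower and 10 higher protein-coding genes. The highest protein-coding gene was inv1 (SPCC191.11, chromosome III, 1723434 to 1726164, 264 probes), the secreted invertase that cells repress in glucose, at 1.35. Levels of inv1 were 0.05 in wild-type, -0.03 in clr3-735, 0.43 in asf1-1 and 1.40 in the double mutant. Its neighbour SPCC1450.01C, a pseudogene of which the array covers only an end, was higher still at 1.57. Ribosomal protein genes had a median of 0.51, above 99.6% of random lists, with 3 of 5 past 0.5: rpl26 at 0.70, rpl802 at 0.67 and rpl1701 at 0.51; the median was 0.21 when arrays were centred on coding probes. All 32 tRNA genes were lower, with a median of -1.04, again a bound. It lay at 0.35% of random lists, which were nearly as low (95% between -1.03 and -0.89) and could again hold tRNA genes themselves.

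Protein-coding genes lower at all of their probes in the double mutant were atg12 (-0.58), mat3-Mi (-0.53), mat1-Mi (SPBC23G7.17C, chromosome II, 2114219 to 2114347), its partner at the expressed cassette, at -0.48, and SPBC18H10.05 (chromosome II, 1779254 to 1781985) at -0.30. Of atg12 and SPBC18H10.05 the array covers only an end, so "all of their probes" refers to that end. The cassettes share sequence, so the mat1-Mi and mat3-Mi probes do not tell them apart. The placement of mat1-Mi is also uncertain. Of the windows over it, that from 3001 to 5050 of the contig matched this place, but that from 4001 to 6050 matched another place best. The probes named mat1-Mi may therefore not carry its sequence. Subtelomeric genes had a median of 0.03 at 2.33% of random lists, which turned to -0.29 with normexp and -0.18 with equal spread; tlh1, a subtelomeric helicase gene with 75.7% of probes saturated, was at 0.63 and the pseudogene SPAC212.09C at 0.56, both bounds, while SPAC977.03 stood at -0.43. The snRNA and snoRNA list had a median of -0.31 (76.4%), with snR92 at -0.94. The mating and nitrogen starvation list had 2 members and a median of 0.82 (98.1%), carried by inv1 (1.35), with isp4, an oligopeptide transporter, at 0.30. Tas3 was at 0.39, pht1 at -0.06, fba1 at -0.14 and SPRRNA.33 at -0.27.

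Against asf1-1, on the same slide, the double mutant was higher over the inv1 block by 0.94 (range of its windows 0.75 to 1.01) and lower over the rDNA by -1.29 (interval -1.53 to -1.15), from the raised asf1-1 level of 0.23 to -1.16, with 0 saturated probes on that slide. Smaller differences were -0.14 in the central domain, -0.23 in the centromeric tRNA clusters, -0.10 in the mating-type region, -0.04 in the outer repeats and in the subtelomere, and 0.06 in the arms. The inv1 block lay above and the rDNA below all random runs in both rankings. The central domain and the tRNA clusters lay below all matched runs (0%, from 2 and 5 separate stretches) but inside runs at any level (6.47% and 6.35%), and with equal spread the central domain turned to 0.04. Under quantile normalization the central domain turned to 0.07 and the tRNA clusters to 0.02, under loess the outer repeats to 0.03, and under coding-probe centring the arms to -0.12.

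Against clr3-735, across slides, the double mutant was lower by -0.57 (interval -0.63 to -0.47) in the central domain, -0.996 in the tRNA clusters, -0.31 in the mating-type region, -0.11 in the outer repeats, -0.12 in the subtelomere and -1.15 in the rDNA, and higher by 1.43 over inv1. The interaction, the difference of the clr3-735 effect between asf1-1 and asf1+ cells, was 0.98 over inv1, -1.58 over the rDNA, -0.40 in the tRNA clusters, -0.18 in the outer repeats, -0.17 in the central domain, -0.12 in the mating-type region, -0.05 in the subtelomere and 0.14 in the arms. Over the alternatives run the interaction ranged from 0.68 to 1.01 over inv1, -1.97 to -0.90 in the rDNA, -0.70 to -0.22 in the tRNA clusters, -0.48 to 0.0019 in the outer repeats, -0.47 to -0.01 in the central domain, -0.42 to -0.02 in the mating-type region, -0.35 to -0.01 in the subtelomere and -0.16 to 0.18 in the arms. At saturated probes the double mutant minus clr3-735 values outside the rDNA are upper bounds; the interaction, which holds 2 saturated arrays, is a bound in neither direction, and saturated probes were 78.4% of the rDNA in wild-type and 82.9% in clr3-735.

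With both alleles fitted over the 4 arrays, tRNA genes were lower on the arrays with asf1-1: limma with Benjamini-Hochberg adjustment found 41 of 204 genes lower and 2 higher. Both arrays with the asf1-1 allele lie on slide 2, so this fit and its p-values cannot tell the allele from the slide. All 32 tRNA genes fell, also when adjusted over the list alone (32), led by SPBTRNAILE.06 at -1.43 (standard error 0.247, adjusted p = 2.32e-06), SPBTRNAILE.05 at -1.40, SPBTRNALEU.06 at -1.40, SPBTRNALEU.07 at -1.40 and SPBTRNAILE.08 at -1.38. Part of this lies in the genomic DNA channel: over tRNA gene probes asf1-1 minus wild-type was -0.49 in Cy5 and 0.25 in Cy3. The other lower genes, named after their values were seen, were SPBC83.19C, SPBC21B10.15, mug124, snR92, SPNCRNA.116, SPNCRNA.352, SPNCRNA.363, SPNCRNA.391 and SPNCRNA.450. The genes that rose in limma were neighbours: inv1 at 0.79 (adjusted p = 0.00732) and the pseudogene SPCC1450.01C (chromosome III, 1726173 to 1727116), of which the array covers only an end. The latter was at 1.05 (adjusted p = 0.000314 with limma), and each was higher in both asf1-1 arrays. The fit averages the asf1-1 effect over clr3+ and clr3 mutant cells, which for inv1 was 0.32 and 1.40 (interaction 0.98). Its p-values use the same standard error for every gene, so they do not reflect how large that gap was for inv1. Adjusted over the list alone, snR92 fell (1 of 4) and inv1 rose (1 of 2), as over all genes, and 0 of 5 ribosomal protein and 0 of 22 subtelomeric genes passed limma either way; at an unadjusted p under 0.05, 9 genes were higher and 46 lower in all. These calls ended (0 and 0 with limma) under normexp, loess, coding-probe centring or without saturated probes, the last over 193 genes. The effect did not shrink there: the median over tRNA genes was -1.11 at first (median standard error 0.247) and -1.49 (0.288), -1.23 (0.186), -1.38 (0.328) and -1.24 (0.283, over 23 genes) in those settings, with 53, 46, 62 and 33 genes lower at an unadjusted p under 0.05. The estimated prior degrees of freedom dropped from infinite to 1.53, 1.37, 1.94 and 1.32, which widens the distribution that p-values are read from, so the calls rest on that estimate. Of the tRNA genes limma also called fewer with trend and robust options (10 of 32), under quantile normalization (29 of 32) and with probes of 1 genome match (7 of 9). Most tRNA gene probes (80.1%) match several places, so the 32 genes are not independent.

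For the clr3-735 allele, limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, with 1 higher and 7 lower at an unadjusted p under 0.05, and 0 of 32 tRNA genes adjusted over the list alone. This fit averages the allele's effects over both backgrounds and takes their difference as error. Where they run opposite ways, as over tRNA genes (0.38 and -0.33), 0 calls do not show that the allele had no effect. Its list medians were 0.03 for tRNA genes, 0.02 for ribosomal protein genes and 0.05 for subtelomeric genes.

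Gene by gene, the difference between asf1-1 and asf1+ cells tended to run the same way in clr3+ and clr3-735 cells. Its size differed, as for inv1 (0.32 and 1.40), and the rDNA as a region went opposite ways (0.56 and -1.15). The clr3-735 effect tended to run opposite ways in asf1+ and asf1-1 cells. Across 204 genes, which are not independent replicates, asf1-1 minus wild-type correlated with double mutant minus clr3-735 at r = 0.77 (rho = 0.79). The correlation of clr3-735 minus wild-type with double mutant minus asf1-1 was r = -0.67 (rho = -0.74). Over single probes the 2 correlations were weaker, at 0.595 and -0.256. These were the 2 relations computed; of 10000 circular shifts, 0% lay as far from 0 for either correlation across genes, and the central range of shifts was -0.21 to 0.25 for the first r and -0.34 to 0.24 for the second. Both contrasts of the first pair are slide 2 minus slide 1, so a difference between the slides alone could give its positive r. The circular shifts cannot tell this apart from an effect of the allele. Both contrasts of the second pair lie within a slide, and with equal spread of the arrays its r was -0.39.

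At gene starts, the nucleosome-depleted region was deeper on the asf1-1 and double mutant arrays. Over 147 protein-coding genes, the depth was -0.55 in wild-type (interval -0.61 to -0.50), -0.48 in clr3-735 (-0.54 to -0.42), -0.97 in asf1-1 (-1.04 to -0.89) and -1.27 in the double mutant (-1.34 to -1.20). The first nucleosome after the start, in the bin from 50 to 100 bp, stood at 0.62, 0.55, 0.43 and 0.53 in the same order. Gene ends showed depths of -0.18, -0.11, -0.39 and -0.61. Divided by each array's standard deviation, the depths at starts were -0.78, -0.66, -1.08 and -1.21, and the strains with the asf1-1 allele are those of slide 2.

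**Figure D4:**
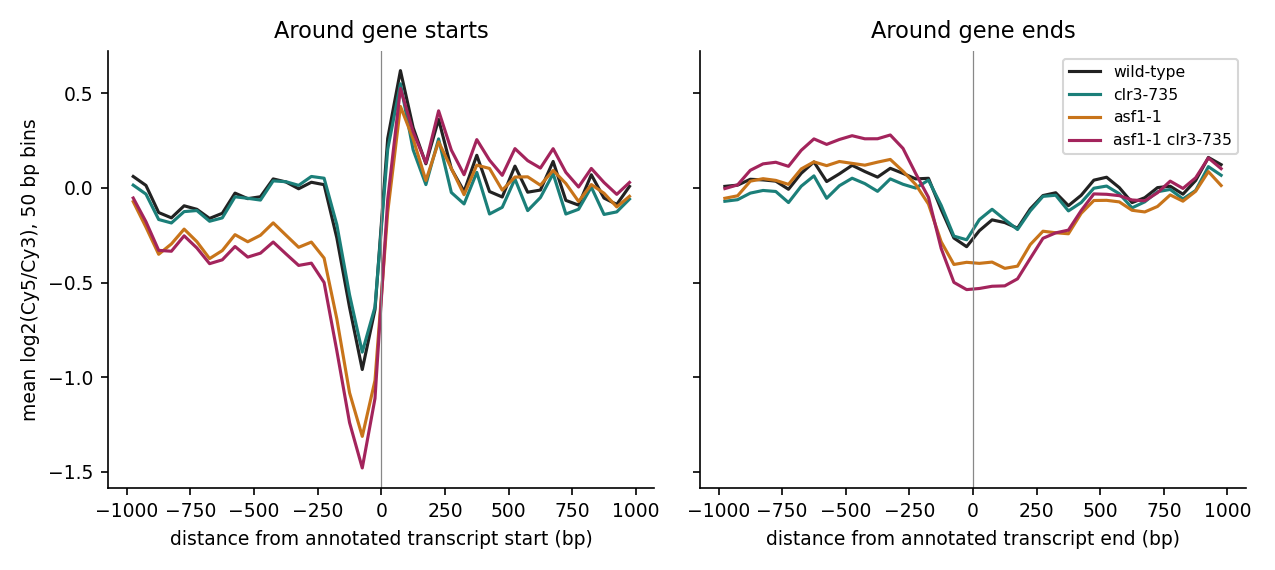
Mean log2(Cy5/Cy3) in 50 bp bins (y axis) by distance in bp from the annotated transcript start or end (x axis) over 147 protein-coding genes; lines are the 4 strains. The lowest bin before the start was -0.96 in wild-type, -0.87 in clr3-735, -1.31 in asf1-1 and -1.48 in the double mutant.

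In 42 genes of at least 2 kb, the first 500 bp differed from wild-type by a median of -0.07 in asf1-1, -0.14 in clr3-735 and 0.04 in the double mutant, and the last 500 bp by -0.03, -0.03 and 0.02. In the genomic DNA channel alone, 0 genes reached the limit of -2 for a sequence difference between strains; the lowest values were -0.28 in asf1-1, -0.29 in clr3-735 and -0.54 in the double mutant, each minus wild-type.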

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

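The tests of saturated spots, slide or scan, extra DNA of the locus in Cy5, less of it in Cy3 and more rDNA in Cy3 were chosen only after the results were seen, as was the use of the genomic DNA limit across slides; those of GC content, wider spread and very bright spots were set before. Of the differences between backgrounds listed first, those in the arms, the tRNA genes and euchromatin were not tested, and none was tested against replicates.

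The clr3-735 allele went with opposite differences in asf1+ and asf1-1 cells in several places. The difference between backgrounds was -0.40 in the tRNA clusters of centromere 2 (0.17 against -0.23), 0.14 in the chromosome II arms (-0.08 against 0.06), -1.58 in the rDNA (0.27 against -1.29), -0.72 over the tRNA genes (0.38 against -0.33) and 0.15 in euchromatin (-0.08 against 0.06). In the tRNA clusters and the rDNA the difference lay below all matched random runs (0%), at 6.83% and 0% of runs at any level. Across genes the allele's effects in both backgrounds correlated at -0.67, farther from 0 than all 10000 circular shifts. Some of these signs depend on scaling. In the arms, the main part of euchromatin, both effects and their difference turned with coding-probe centring (0.04 against -0.12, difference -0.16) and with probes of 1 genome match (0.0094 against -0.03, difference -0.03). In the tRNA clusters the effect in asf1-1 cells turned to 0.02 under quantile normalization. Each background was measured on its own slide, with 1 array per strain. The genomic DNA channel, looked at alone, passed a limit of 0.3 set for regions in the rDNA and over inv1. In the rDNA it was higher by 0.42 in the double mutant than in asf1-1, within slide 2, and across slides by 0.42 in asf1-1 and 0.89 in the double mutant than in wild-type and by 0.88 in the double mutant than in clr3-735, with a difference between backgrounds of 0.42. Across slides saturated Cy3 spots (24.9% of the rDNA in wild-type, 21.7% in clr3-735) add to these. Over inv1 it was lower in the double mutant, by -0.40 against wild-type and -0.41 against clr3-735.

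The lower ratio over the central domain of centromere 2 on the arrays with asf1-1 could come from saturated spots on slide 1, GC content, the wider spread of ratios on slide 2, or the slide itself. Over the 1094 probes saturated on neither array the asf1-1 minus wild-type median was -0.46 (interval -0.47 to -0.44), or -0.39 when the arrays were centred anew on unsaturated probes, and with the GC trend removed it was -0.34 (interval -0.36 to -0.32), which argues against both as the whole cause. Cy5 alone was at -0.28 and Cy3 at 0.12, so the genomic DNA makes up part of it. For the spread, the region's 12 windows lay -0.32 (interval -0.41 to -0.25) from the line of asf1-1 on wild-type in the arms (slope 1.21), and with equal spread the difference was -0.35 (interval -0.37 to -0.33), which argues against spread as the whole cause. A further limit set before, the 2.5% point of single arm windows (-0.70), was dropped because a median of 12 windows varies less than single ones. Among 210 overlapping arm runs of 12 windows, a comparison chosen after the results were seen, the region lay at 4.29%, so departures from the line as large as this also occur in the arms. The number of slides holding both asf1 states was 0, so slide or scan and the asf1-1 allele cannot be told apart. An effect of the asf1-1 allele on centromeric nucleosomes remains among the open explanations.

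The higher ratio over inv1 in the double mutant was seen against asf1-1 on the same slide. Extra DNA of the locus added to the Cy5 sample would flatten its log2 profile. The standard deviation of Cy5 over the block was 1.11 times that in asf1-1 (0.86 against 0.78). This cannot decide the question, because ratios on the double mutant array were wider throughout (standard deviation 1.05 against 0.90). Extra DNA in Cy5 therefore stays open. Less DNA of the locus in the Cy3 sample alone would leave Cy5 as in asf1-1, but Cy5 was higher by 0.60 (interval 0.57 to 0.62), so this cannot be the whole cause, although Cy3 was lower by -0.26. Copies of the locus in the strain would change both channels alike. Cy5 was higher and Cy3 lower than in asf1-1, which argues against copies as the cause of the higher ratio on these arrays. A difference between the cultures in growth state or the double mutation itself may be the cause, and neither was tested with replicates.

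The lower ratio over the rDNA in the double mutant was also seen within slide 2. More rDNA in the Cy3 sample alone would leave Cy5 as in asf1-1, but Cy5 was lower by -0.92 (interval -0.94 to -0.89). This cannot be the whole cause of the difference from asf1-1, although Cy3 was higher by 0.42. Against wild-type, across slides, Cy5 was at 0.07 and Cy3 at 0.89, so the measured fall lay in the genomic DNA channel. Both channels held saturated spots on slide 1, so that split is uncertain. Loss of ratio at very bright spots would lower other probes as bright in Cy3. The 3271 other probes within the main Cy3 range of the rDNA had a median of -0.10 (interval -0.11 to -0.08). They were not matched to the rDNA in brightness within that range. On the wild-type array Cy3 was saturated at 24.9% of rDNA probes but 0.013% of arm probes. The test therefore cannot decide for the brightest rDNA spots, where a loss of ratio stays open. A difference between strains in nucleosome recovery from the rDNA, or between the DNA preparations, may remain and was not tested.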

How the results depend on the processing

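The percentiles among runs at any level, the loess, quantile and coding-probe values of the gene lists and of the correlations across genes, and those correlations over protein-coding genes were chosen only after the results were seen. Of the values that answer a comparison, 231 kept their direction and stayed within their interval or on their side of the threshold, 241 moved, 21 reversed, 5 lost and 1 gained a place outside the random runs; for the others the numbers were 194, 233, 27, 4 and 1. The central domain stayed lower in asf1-1 and in the double mutant than in wild-type in every setting run, as did the mating-type region, and the rDNA stayed lower and the inv1 block higher in the double mutant than in asf1-1. Limma called 0 genes for the clr3-735 allele in each setting, which shows no stability, because the fit averages effects that run opposite ways in both backgrounds and takes their difference as error. The correlation across genes of the clr3-735 effects ranged from -0.70 to -0.39 and that of the asf1-1 effects from 0.71 to 0.93 (Pearson); over protein-coding genes alone they were -0.59 and 0.82. Signal over background limited little, since leaving out dim probes changed no value past its interval. The limma fit pairs the clr3-735 effect by slide, and the asf1-1 effect lies between slides. A subtelomere of 100 kb was not run, since the array covers 50 kb of it. With 1 genome match no rDNA probe is left, and the GC and single-match settings lack the part of the contig absent from the reference, 59.1% of the mating-type probes. Centring on coding probes shifts every value by -0.12 in asf1-1, 0.12 in clr3-735 and -0.30 in the double mutant (each minus wild-type), by -0.18 and -0.42 in the double mutant minus asf1-1 and minus clr3-735, and by -0.30 in the interaction. Leaving out saturated probes centres the arrays anew, which shifts every value by 0.065, 0.061, 0.017, -0.048, -0.045 and -0.11 in the order given below, and keeping probes with 1 genome match does so by 0.031, 0.085, -0.055, -0.086, -0.14 and -0.17. These shifts make up the turned signs of the inv1 block and the arms in those settings, where few probes were lost. The limma calls for asf1-1 ended where the prior degrees of freedom dropped (infinite at first; 1.53 with normexp, 1.37 with loess, 1.94 with coding-probe centring, 1.32 without saturated probes), while the median effect over tRNA genes went from -1.11 to -1.49, -1.23, -1.38 and -1.24. Other causes were not tested.

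Values that moved or reversed are given by setting, with regions in the order asf1-1, clr3-735 and double mutant minus wild-type, double mutant minus asf1-1 and minus clr3-735, and interaction. Normexp gave -0.21, 0.17, -0.24, -0.041, -0.39 and -0.19 in the outer repeats, -0.64, 0.029, -0.72, -0.14, -0.72 and -0.16 in the central domain, -0.39, -0.066, -0.47, -0.13, -0.46 and -0.092 in the mating-type region, and -0.25, 0.027, -0.33, -0.076, -0.38 and -0.079 in the subtelomere. It turned signs in the inv1 block (0.011 for clr3-735 minus wild-type). In the same setting limma called 0 genes higher and 0 lower for asf1-1 (20 and 53 at an unadjusted p under 0.05), 16 genes were at least 0.5 higher in clr3-735, and the depths at gene starts were -0.42 in wild-type, -0.58 in clr3-735, -1.16 in asf1-1 and -1.47 in the double mutant. Its list medians were 0.42 for ribosomal protein genes in asf1-1, -0.26 and -0.29 for subtelomeric genes in asf1-1 and the double mutant, -1.04, 0.50 and -1.38 for tRNA genes in asf1-1, clr3-735 and the double mutant, and, with turned signs in clr3-735, 0.0081 for mating and nitrogen starvation and 0.019 for snRNA and snoRNA. Loess within arrays gave -0.18, 0.035, -0.15, 0.029, -0.19 and 0.0019 in the outer repeats, -0.25, 0.11, -0.27, -0.047, -0.40 and -0.16 in the central domain, -0.10, 0.031, -0.13, -0.030, -0.16 and -0.074 in the mating-type region, and -0.10, -0.0041, -0.16, -0.061, -0.16 and -0.043 in the subtelomere. Signs turned in the rDNA (-0.037 for asf1-1 minus wild-type), in the inv1 block (0.020 for clr3-735 minus wild-type) and in the arms (0.042 for asf1-1 minus wild-type and 0.013 for clr3-735 minus wild-type). Limma then called 0 higher and 0 lower for asf1-1 (38 and 46 unadjusted), and 2, 1 and 7 genes were at least 0.5 higher in asf1-1, clr3-735 and the double mutant; tRNA genes had medians of -0.96, 0.18 and -1.31 and subtelomeric genes -0.025 in clr3-735. Quantile normalization gave 0.056, 0.16, 0.018, -0.027, -0.13 and -0.18 in the outer repeats, -0.29, 0.063, -0.22, 0.071, -0.29 and -0.014 in the central domain, -0.16, -0.015, -0.18, -0.015, -0.14 and -0.020 in the mating-type region, and -0.053, 0.0084, -0.058, -0.0080, -0.060 and -0.012 in the subtelomere. It turned signs in the tRNA clusters (0.018 for double minus asf1-1) and in the left part of the contig (0.12 for double minus clr3-735). Here limma called 7 genes higher for asf1-1, 27 genes were at least 0.5 lower in asf1-1, 11 higher in clr3-735 and 30 lower in the double mutant, and tRNA genes had medians of 0.44 in clr3-735 and -0.62 in the double mutant. Coding-probe centring gave -0.072, 0.28, -0.27, -0.22, -0.53 and -0.48 in the outer repeats, -0.58, 0.14, -0.85, -0.32, -0.99 and -0.47 in the central domain, -0.35, 0.11, -0.62, -0.28, -0.73 and -0.42 in the mating-type region, and -0.18, 0.14, -0.39, -0.22, -0.54 and -0.35 in the subtelomere. It turned signs in the inv1 block (0.077 for clr3-735 minus wild-type), in the arms (0.043 for clr3-735 minus wild-type, -0.29 for double minus wild-type, -0.12 for double minus asf1-1, -0.33 for double minus clr3-735 and -0.16 for the interaction) and in the left part of the contig (-0.16 for the interaction). With it limma called 0 higher and 0 lower for asf1-1 (1 and 62 unadjusted), 17 genes were at least 0.5 higher in clr3-735 and 2 in the double mutant, ribosomal protein genes had a median of -0.10 in clr3-735, subtelomeric genes 0.14 in clr3-735 and -0.28 in the double mutant, and tRNA genes 0.50 and -1.35. Equal spread gave 0.0086, 0.16, -0.061, -0.077, -0.20 and -0.23 in the outer repeats, -0.35, 0.061, -0.30, 0.041, -0.36 and -0.045 in the central domain, -0.21, -0.021, -0.27, -0.053, -0.21 and -0.062 in the mating-type region, and -0.11, 0.0002, -0.16, -0.064, -0.16 and -0.061 in the subtelomere. Signs turned in the left part of the contig (0.0037 for double minus clr3-735). Under it limma called 4 genes higher for asf1-1, 11 genes were at least 0.5 higher in clr3-735 and 6 in the double mutant, the depths were -0.69 in wild-type, -0.54 in clr3-735 and -0.99 in the double mutant, and tRNA genes had a median of -0.72 in the double mutant. GC correction gave 0.11, 0.16, 0.14, 0.013, 0.0024 and -0.14 in the outer repeats, -0.34, -0.0067, -0.31, -0.0071, -0.30 and -0.019 in the central domain, -0.20, 0.0028, -0.24, -0.038, -0.25 and -0.077 in the mating-type region, and -0.022, 0.024, -0.015, -0.018, -0.040 and -0.044 in the subtelomere. It turned signs in the arms (-0.0082 for double minus wild-type). After it 2 genes were at least 0.5 higher in the double mutant, the depths were -0.43, -0.38, -0.75 and -0.95 in wild-type, clr3-735, asf1-1 and the double mutant, and tRNA genes had a median of -1.29 in the double mutant. Without saturated probes the regions gave -0.18, 0.20, -0.30, -0.14, -0.48 and -0.33 in the outer repeats, -0.39, 0.081, -0.52, -0.18, -0.60 and -0.27 in the central domain, -0.23, 0.013, -0.41, -0.18, -0.45 and -0.25 in the mating-type region, and -0.11, 0.043, -0.22, -0.15, -0.31 and -0.19 in the subtelomere, and signs turned in the inv1 block (0.018 for clr3-735 minus wild-type). Over 193 genes limma called 0 higher and 0 lower for asf1-1 (28 and 33 unadjusted), and 2 genes were at least 0.5 higher in asf1-1. Probes with 1 genome match gave -0.044, 0.20, -0.25, -0.19, -0.40 and -0.39 in the outer repeats, -0.38, 0.073, -0.55, -0.18, -0.60 and -0.26 in the central domain, -0.31, 0.11, -0.54, -0.28, -0.66 and -0.40 in the mating-type region, and -0.24, 0.085, -0.38, -0.17, -0.50 and -0.25 in the subtelomere. They turned signs in the inv1 block (0.043 for clr3-735 minus wild-type), in the arms (0.0094 for clr3-735 minus wild-type, -0.039 for double minus wild-type, -0.026 for double minus asf1-1, -0.042 for double minus clr3-735 and -0.031 for the interaction) and in the left part of the contig (-0.0074 for the interaction). Over the 163 genes left, limma called 5 higher and 20 lower for asf1-1, 2 genes were at least 0.5 higher and 17 lower in asf1-1, 4 higher and 1 lower in clr3-735, and 24 lower in the double mutant. Means over probes gave 0.11, 0.15, 0.077, -0.037, -0.073 and -0.19 in the outer repeats, -0.45, 0.051, -0.59, -0.14, -0.64 and -0.19 in the central domain, -0.19, -0.039, -0.38, -0.18, -0.34 and -0.15 in the mating-type region, and -0.042, 0.018, -0.098, -0.056, -0.12 and -0.075 in the subtelomere. They turned the arms (-0.038 for double minus wild-type), and 4 genes were at least 0.5 higher in clr3-735. A subtelomere of 25 kb gave 0.0063, 0.038, 0.022, -0.015, -0.014 and -0.036. A size of 0.3 gave 19 higher genes in asf1-1, 23 higher and 3 lower in clr3-735 and 38 higher in the double mutant, and a size of 1 gave 0 higher and 7 lower in asf1-1, 0 higher in clr3-735 and 2 higher and 26 lower in the double mutant. Limma with trend and robust options called 13 genes higher and 14 lower for asf1-1. The start window from -150 to 50 bp gave depths of -0.40, -0.34, -0.78 and -1.05 in wild-type, clr3-735, asf1-1 and the double mutant. Among runs at any level, the central domain lay at 1.60, 78.2, 5.45, 6.47, 6.58 and 11.8%.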

Other observations

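The values of this part were looked for after the data were seen, and all tests here were chosen then.

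Over 417 windows of 1 kb outside the rDNA, the largest losses in asf1-1 against wild-type were in the window that ends at the start of scr1 and lies mostly upstream of it (chromosome II, 1753001 to 1754050) with -1.11, in one mostly upstream of rga7 on the contig (3001 to 4050) with -1.06, and in one that holds SPNCRNA.116 (1751001 to 1752050) with -1.04. The genes scr1 and rga7 themselves had medians of -0.34 and 0.07. The highest window, at 0.85, lay in the outer repeats (1611001 to 1612050), where saturated probes make it a bound. In clr3-735 the lowest window was in the mating-type region (contig, 23001 to 24050) at -0.36 and the highest was at the edge of the rDNA (chromosome III, 23001 to 24050) at 0.43, followed by 0.42 at 25001 to 26050, with many saturated probes in the first. In the double mutant the lowest was at mug124 (chromosome II, 1688001 to 1689050) at -1.52, and outside inv1 the highest was at sce3 (1777001 to 1778050) at 0.98. The windows had a standard deviation of 0.31 in asf1-1, 0.13 in clr3-735 and 0.43 in the double mutant, each minus wild-type.

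Long terminal repeats (317 probes) differed from wild-type by -0.51 in asf1-1, 0.09 in clr3-735 and -0.69 in the double mutant, with 11.4% of them saturated in wild-type. The hrp1 block (chromosome I) was at 0.17, -0.12 and 0.30 in the same order, and the nmt1 block (chromosome III) at 0.13, -0.12 and 0.19. At the left boundary of centromere 1 the values were -0.03, 0.08 and -0.05, at that of centromere 3 -0.10, 0.15 and -0.13, and beyond the rDNA on chromosome III -0.15, 0.06 and -0.22. None of these blocks and boundaries was outside matched random runs in those comparisons; the repeats were not ranked.

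Along the chromosome II arms the autocorrelation of the ratio had a peak at 320 bp in wild-type, 300 bp in clr3-735, 340 bp in asf1-1 and 310 bp in the double mutant. In wild-type and clr3-735 this was the second peak. On slide 2 the values fell steadily up to 260 bp, with no earlier peak. The rise of these peaks over the trough before them was 0.12, 0.11, 0.027 and 0.013 in the same order, so on slide 2 their place is poorly set. The autocorrelation at 100 bp was 0.033, -0.019, 0.30 and 0.38, and at 400 bp -0.024, -0.011, 0.11 and 0.11. The range searched for the peak was widened after a first version met its edge.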
